A study of Drosophila melanogaster with 6 samples.

How the data were processed

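Gene expression was measured by RNA sequencing of heads of 3-day-old male *Drosophila melanogaster* grown at 18 C. There were 3 libraries from Adar5G1 mutant flies, whose strain label also carries y and sc, and 3 from w1118 flies. The labels give the molecule as polyA RNA, and the extraction protocol states depletion of ribosomal RNA. Libraries were made with the KAPA RNA-Seq Kit and sequenced as 75-bp paired ends on a NextSeq 500, per the labels' protocols. Nothing in the labels says whether the 3 libraries of a group came from separate crosses or collections, so p-values measure only the spread between these libraries, which may be technical. Each genotype was represented by 1 stock.

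The deposited values are whole-number fragment counts per gene, 1 library per file. Per the file headers, the authors counted fragments with featureCounts 1.4.5-p1 as reverse-stranded, by exon and gene, on FlyBase annotation release 5.53. A fragment overlapping several genes was counted for each of them, and the option to count multi-mapping reads was not set. Per the submitters' processing notes, TopHat was used and the build was dm3 (BDGP5). The TopHat version is not given in the sources used here. Counts of near-identical gene copies can therefore be too low or split between copies, and genes sharing exons on 1 strand share counts. Coordinates are those of the deposited files (dm3), from the first to the last exon of a gene. Gene symbols came from a table of gene IDs: 15924 of 16641 IDs were paired with a symbol and 717 were not. Biotypes came from a BDGP6 annotation, matched by ID only.

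The 1 row without a gene ID, which held 0.369% to 0.633% of a library's counts, was left out of library sizes and tests. Counts over genes ranged from 6872569 to 21639081 per library. Rows of ribosomal RNA or of non-coding genes on unplaced scaffolds took 11.0%, 26.0% and 23.8% of the counts in the Adar5G1 libraries and 4.42%, 22.5% and 42.5% in the w1118 libraries. Pairs of libraries were compared by a chi-square of their counts over genes. The lowest chi-square per degree of freedom was 4.36, between w1118 replicates 1 and 2, and the highest within a group 23.9, between Adar5G1 replicates 1 and 3, so no 2 libraries agreed within sampling noise and each was counted as 1 replicate.

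The test was fixed before the data were examined. Counts were analysed with edgeR 4.0.16 in R 4.3.3: filterByExpr with its default minimum of 10 counts, TMM factors, and the quasi-likelihood F test with group as the only term. P-values were adjusted by the Benjamini-Hochberg method and the threshold was an adjusted p of 0.05. Standard errors of log2 fold changes were taken as the fold change divided by the square root of F, which is approximate. Values per gene are CPM scaled by the TMM factors, as mean ± SD. Where all libraries of 1 group had 0 counts, the fold is a lower bound against 3 counts over the group. Where a group had 1 to 3 counts in all, the fold is the ratio of summed counts with its exact 95% counting interval. For these bounds and ratios, counts were first divided by the group's summed library sizes after TMM scaling. Such intervals and bounds cover counting error only.

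There were 23 gene lists, fixed before the data were examined, with 503 names, of which 477 were matched. A list of 2 or more tested genes was tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, adjusted over 22 lists, with camera at an estimated correlation and fry beside it. The male reproductive tract list had 1 tested member and no list test. The share of changed genes on X was compared with that on 2L, 2R, 3L, 3R and 4 by a 2-sided Fisher's exact test, and X below 5 Mb with the rest of X in the same way.

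Named genes followed a rule fixed beforehand. It took Adar, w, y and sc. It took the 6 largest rises and 6 largest falls past the threshold with a mean of at least 5 CPM and no overlap between groups. It took the 3 smallest p-values in each direction and, from each list, up to 3 members past the threshold with the smallest p. Where no member of a list passed, it took the member with the highest mean CPM.

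The alternatives fixed beforehand were DESeq2 1.42.0, RLE, upper-quartile and total-count scaling, no filter and a stricter filter, limma-voom, robust dispersion, the replicate number as a block, an adjusted p of 0.01, a 2-fold minimum, removal of named non-coding, mitochondrial and histone rows, removal of X-linked genes, and leaving out each library. Protein-coding genes only, counts thinned to the smallest library, and leaving out both libraries numbered 3 were chosen after seeing the data.

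The test was tried on simulated data: 10201 genes with the unscaled library sizes and dispersions of this comparison, 200 of them changed. Means were pooled over the 6 libraries. Composition differences between libraries, whose TMM factors ran from 0.764 to 1.25 in the data, were not simulated. Over 10 draws edgeR recovered 41.8% of genes changed 1.5-fold, 81% at 2-fold, 91.4% at 4-fold and 98.8% at 8-fold. Of 1711 simulated calls 145 were false, 8.47%, above the nominal 5%, with 5.39% to 12.1% in single draws. The simulation was first run as a single draw, whose 12.1% of false calls exceeded the limit of 10% set for it. The average over 10 draws was adopted after that, with the limit kept. False calls averaged 8.28% with limma-voom and 11.1% with DESeq2. The counts of changed genes below may carry such an excess too. Its size cannot be carried over, since 200 genes were changed in the simulation and 1423 were called in the data. In a single draw each, unchanged counts gave 0 calls and 0 of 22 lists, and a list lowered 1.5-fold was the 1 list called. Simulated genes were drawn independently, so this does not test list calls where members move together. In the data the estimated correlation was 0.61 in the antimicrobial peptide list and 0.35 in the Toll list.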

Results

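Head RNA was profiled in 3 libraries of Adar5G1 males and 3 of w1118 males. Adar encodes the fly adenosine deaminase acting on RNA, which converts adenosines to inosines in transcripts. The w1118 stock is a laboratory strain with a mutated white gene and served as the wild type. Counts over genes were 12040951, 7189944 and 21639081 in Adar5G1 replicates 1, 2 and 3, and 6872569, 17709643 and 12121889 in w1118 replicates 1, 2 and 3. The comparison asked which head transcripts differed in abundance between the mutant and the wild type.

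Adar itself (FBgn0026086, X:1667758-1682098, plus strand) was nearly absent from the mutant. It had 5, 1 and 19 counts in the Adar5G1 libraries and 2860, 6142 and 2602 in the w1118 libraries, or 0.476 ± 0.392 against 317.9 ± 32.2 CPM (SD, n = 3 each). Its log2 fold change was -9.04 (SE 0.26, edgeR adjusted p = 1.31e-06). Without Adar5G1 replicate 3, which held 19 of the remaining counts, the log2 fold change of Adar was -10.02. Some of its exons overlapped FBgn0261548 on the same strand, so the few remaining counts need not come from Adar. The white gene w (FBgn0003996, X:2684632-2690499), which encodes an eye pigment transporter, had 16.7 ± 2.98 CPM in Adar5G1 and 3 counts in all in w1118. The ratio of summed counts, scaled by library size, was 212 (95% counting interval 72.3 to 1031). The yellow gene y (FBgn0004034, X:250542-255278), a body pigmentation gene, had 2 counts over the Adar5G1 libraries and 12 over the w1118 libraries, too few to be tested. The scute gene sc (FBgn0004170, X:290093-291530) had 0 counts in each library.

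Of 10201 genes tested, 900 rose and 523 fell in Adar5G1 (edgeR quasi-likelihood test). Changes of at least 2-fold made up 448 of the rises and 167 of the falls. The groups did not overlap for 3218 genes, 31.6% of those tested, where chance gives 10%. Adar5G1 replicate 3 had a chi-square per degree of freedom over genes of 23.9 and 20.7 against replicates 1 and 2, which had 6.97 between them. Its values against w1118 replicates 1, 2 and 3 were 29.1, 49.1 and 37.1. In w1118, replicate 3 had 6.12 and 12.1 against replicates 1 and 2, which had 4.36 between them. This measure grows with depth, and Adar5G1 replicate 3 was the deepest library. On the first principal component, with 75.4% of the variance, Adar5G1 replicates 1, 2 and 3 lay at -29.9, -30.3 and -21.4. The w1118 libraries lay between 22.8 and 31.1. Among genes with a mean of at least 5 CPM over the 6 libraries and no overlap between the groups, the 6 rises with the highest fitted fold changes were those of DptA, sordd2, CG14204, DptB, Dro and AttC. Fitted values do not rank genes with 0 counts in a group, so bounds or count ratios are given for these. The antibacterial peptide gene DptA (FBgn0004240, 2R:14753270-14753765) had 71.1 ± 28.2 CPM in Adar5G1 and 0 counts in w1118, at least 737-fold higher. The gene sordd2 (FBgn0052581, X:15690941-15693195) had 32.6 ± 2.65 CPM and was at least 401-fold higher, and CG14204 (FBgn0031032, X:19477650-19481090) had 26.1 ± 1.21 CPM and was at least 310-fold higher. Both also had 0 counts in w1118. By the same rule the falls after Adar were those of the photolyase gene phr (FBgn0003082, 2R:3712794-3714824), 0.732 ± 0.148 against 18.7 ± 1.35 CPM, and CG6912 (FBgn0038290, 3R:10960860-10962726), 2.41 ± 0.377 against 59.8 ± 8.40 CPM. Of the others, CG8757 was 19.1-fold, CG3270 16.7-fold and the cytochrome P450 gene Cyp12a4 16.2-fold lower. The smallest p-values among rises were those of the cytochrome P450 genes Cyp6a17 (39.5-fold, adjusted p = 1.31e-06) and Cyp6a2 (4.03-fold), and CG8665 (11.97-fold). With upper-quartile scaling the split was 812 higher and 764 lower, and with total counts only 582 and 209. Without w1118 replicate 1 there were 545 rises and 331 falls.

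Of 11 tested antimicrobial peptide genes 7 rose, 1 fell and 3 did not pass, and 10 rose and 1 fell adjusted over the list alone. The list held 17 names, of which 16 were matched. Drs was not matched, since its current ID was absent from the deposited genes, so it was not measured here. DptA, CecA2 and CecC had 0 counts in w1118 and passed the count filter through Adar5G1 only. So did AttA, AttC, DptB, Dro and Mtk, with 14, 11, 2, 13 and 20 counts over the w1118 libraries. A member near 0 in w1118 was thus tested only if it was expressed in Adar5G1. The filter therefore favours rises in the share, the median and the list test. With robust dispersion 5 rose and 0 fell, and 10 rose with total counts only and without Adar5G1 replicate 2 or 3. Besides DptA, the genes DptB (FBgn0034407, 2R:14754896-14755400), Dro (FBgn0010388, 2R:10633466-10634219), AttC (FBgn0041579, 2R:9281210-9282172) and Mtk (FBgn0014865, 2R:11296351-11296618) encode secreted peptides that act against bacteria or fungi. Dro had 254.6 ± 143.2 CPM in Adar5G1 and 0.424 ± 0.302 in w1118, a log2 fold change of 9.41 (SE 0.62, edgeR adjusted p = 5.9e-05). Mtk had 259.6 ± 98.3 against 0.634 ± 0.262 CPM (8.82, SE 0.41), and AttC 186.5 ± 115.5 against 0.357 ± 0.209 CPM (9.19, SE 0.69). DptB had 100.1 ± 81.5 CPM in Adar5G1 and 2 counts over w1118, a count ratio scaled by library size of 1694 (counting interval 469 to 13996). Adar5G1 replicate 1 was the highest for DptB (192.7 CPM, against 68.65 and 39.03 in replicates 2 and 3), Dro (417.4, against 148.4 and 198.1), AttC (317.4, against 143.2 and 98.98) and Mtk (370.8, against 223.8 and 184.2). Without it the log2 fold changes of DptB, Dro and AttC were 9.66, 8.85 and 8.56. The fall was that of Drsl5, named after its values were seen, with a log2 fold change of -0.61 (SE 0.17). The median log2 fold change was 8.82, or 6.57 with the genes at 0 counts set to their bounds (camera adjusted p = 7.5e-21, and adjusted p = 0.207 with an estimated correlation). Over the settings with the preset correlation the fitted median ran from 6.20 to 9.21. AttA and AttB are close copies, and their separate counts are uncertain.

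**Figure D1:**
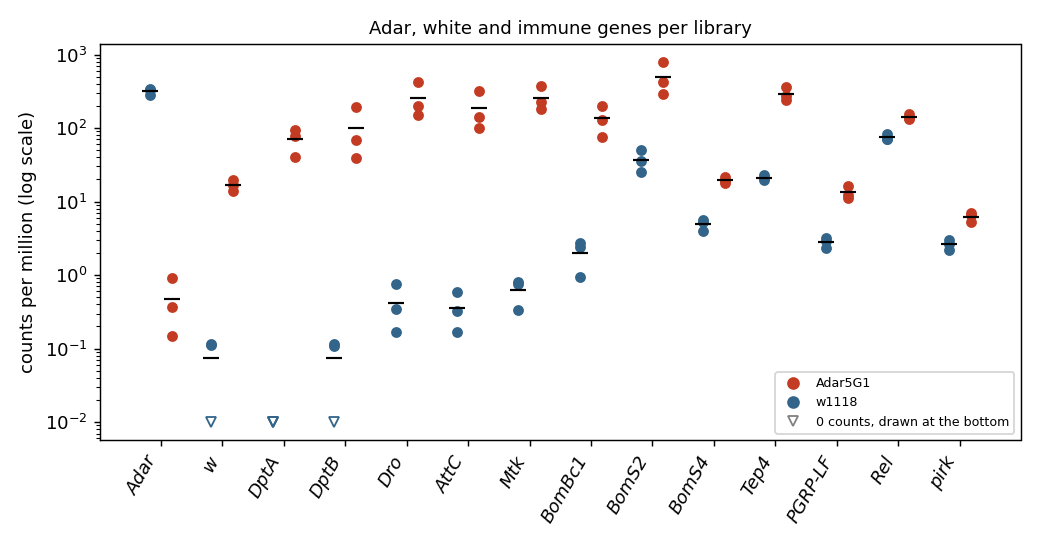
CPM on a log scale for Adar, w and 12 immune genes in each of 3 w1118 (blue) and 3 Adar5G1 (red) libraries. Points are libraries, black lines are group means, and open triangles at the bottom are libraries with 0 counts. Adar lies below 1 CPM in each Adar5G1 library, and each of the 12 immune genes lies higher in each Adar5G1 library than in any w1118 library.

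In the Toll pathway and Bomanin list 19 of 26 tested genes rose and 0 fell, and 21 rose adjusted over the list alone (camera adjusted p = 1.02e-17, and adjusted p = 0.225 with an estimated correlation). Bomanins are short secreted peptides induced through Toll. BomBc1 (FBgn0034328, 2R:14270209-14270740) had 135.1 ± 63.0 against 2.03 ± 0.948 CPM, BomS2 499.1 ± 254.7 against 36.7 ± 12.2 CPM, and BomS4 19.4 ± 1.98 against 4.95 ± 0.848 CPM. Adar5G1 replicate 1 was again the highest for BomBc1 (201.6 CPM, against 127.6 and 76.23) and BomS2 (783.5, against 421.9 and 291.9). In the IMD list 8 of 21 rose and 0 fell, with 8 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.00398, and adjusted p = 0.225 with an estimated correlation). Without w1118 replicate 1 or 2, and with robust dispersion, 5 rose, and with upper-quartile scaling 8 rose and 2 fell. The peptidoglycan recognition protein gene PGRP-LF was 4.78-fold higher, Rel, the NF-kappaB factor of the pathway, 1.87-fold, and pirk, a negative regulator of the pathway, 2.40-fold. In the JAK/STAT and stress-induced list 4 of 11 rose, as many as adjusted over the list alone (camera adjusted p = 8.56e-04, and adjusted p = 0.251 with an estimated correlation). Its median log2 fold change was 0.08 and its mean 0.49, and the IMD list had 0.10 and 0.89. Both list calls thus rest on part of the members, and the typical member hardly moved in the main fit. Over settings the JAK/STAT median ran from -0.03 to 0.72 and the IMD median from 0.04 to 0.28. The thioester-containing protein gene Tep4 (FBgn0041180, 2L:19548507-19556451) was 13.9-fold higher (292.6 ± 63.9 against 20.99 ± 1.73 CPM), Vago 2.42-fold and vir-1 1.52-fold. Of 14 RNA interference and antiviral genes 1 rose, Dcr-2 (1.36-fold, edgeR adjusted p = 0.0264), also 1 adjusted over the list alone, and its list was not called (camera adjusted p = 0.824). The call of Dcr-2 was lost without Adar5G1 replicate 1 or 2 and without w1118 replicate 1 or 2, and that of vir-1 with total counts only. The hemocyte list had 0 of 11 members past the threshold with edgeR, 1 with DESeq2 and 0 with limma-voom, 2 at an unadjusted p under 0.05, and 0 adjusted over the list alone (camera adjusted p = 0.335), and without w1118 replicate 2 the list passed (adjusted p = 0.0225) with 2 members lower. Col4a1, its most abundant member, had 265.5 ± 64.3 CPM in Adar5G1 and 267.8 ± 52.6 in w1118.

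Of 25 tested phototransduction and photoreceptor genes 12 fell and 1 rose, with 15 lower and 1 higher adjusted over the list alone. The carotenoid oxygenase gene ninaB (FBgn0002937, 3R:9526287-9528886) had 42.9 ± 6.95 against 109.9 ± 9.70 CPM, a log2 fold change of -1.37 (SE 0.12, edgeR adjusted p = 3.2e-04). The channel gene trpl (FBgn0005614, 2R:5641202-5653023) had 840.7 ± 52.7 against 1709 ± 127 CPM (-1.02, SE 0.10), and the G protein subunit gene Gbeta76C 385.7 ± 25.3 against 557.9 ± 8.85 CPM (-0.53, SE 0.07). The rise was that of the opsin gene Rh4 (1.26-fold), named after its values were seen. The call of Gbeta76C was lost with total counts only. With total counts only 2 of these genes fell and 0 rose. Without Adar5G1 replicate 1, w1118 replicate 1 or w1118 replicate 2, 6, 7 and 7 fell and 0 rose. The list stayed called, lower, in each of these (camera adjusted p at most 0.00345). The median log2 fold change of the list was -0.33 (camera adjusted p = 1.23e-05, and adjusted p = 0.317 with an estimated correlation). Among 16 eye pigment genes 2 rose, w among them, and 4 fell, the same numbers adjusted over the list alone (camera adjusted p = 0.906). Without Adar5G1 replicate 3, 4 rose and 4 fell, and with total counts only 2 rose and 2 fell. The pteridine pathway gene pr fell 1.99-fold and the transporter gene bw 1.76-fold.

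**Figure D2:**
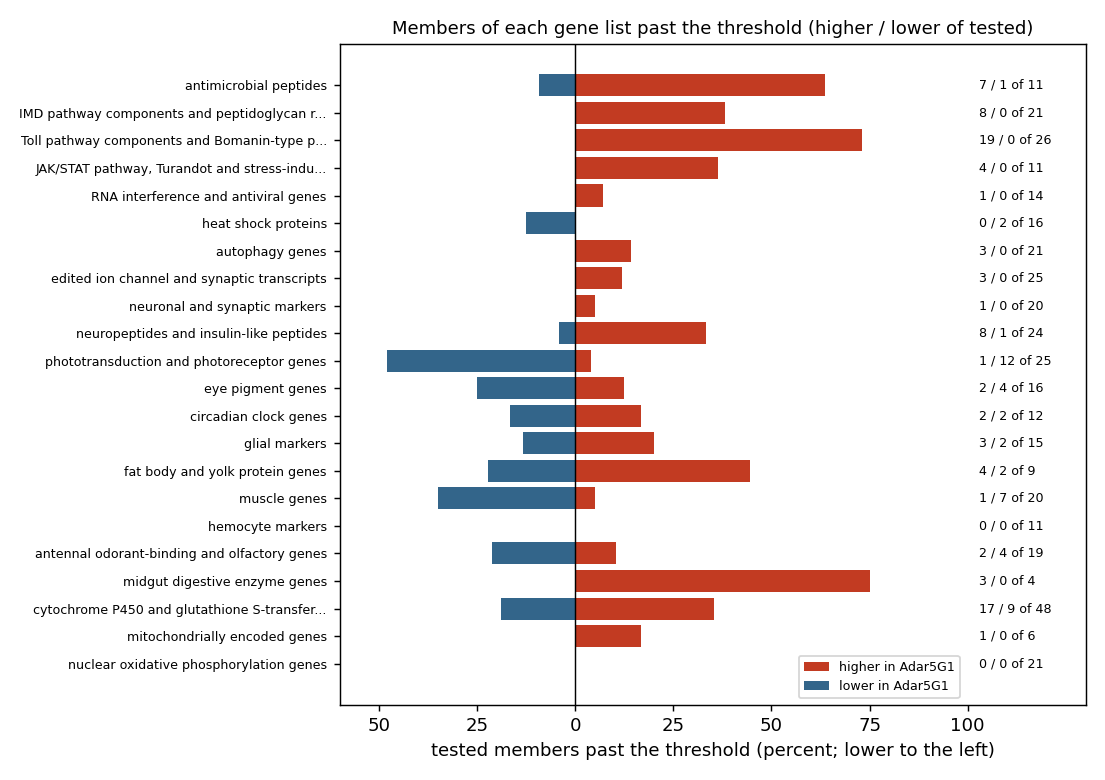
Percent of tested members of each gene list past the edgeR threshold, with genes higher in Adar5G1 to the right (red) and lower to the left (blue), and the numbers at the right edge. The antimicrobial peptide list has 7 of 11 higher and the phototransduction list 12 of 25 lower.

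Of 48 cytochrome P450 and glutathione S-transferase genes 17 rose and 9 fell, with 20 and 16 adjusted over the list alone (camera adjusted p = 0.0258, and adjusted p = 0.922 with an estimated correlation). Without Adar5G1 replicate 1, 15 rose and 5 fell, without w1118 replicate 1, 12 and 4, and with upper-quartile scaling 16 and 14. Cyp6a17 (FBgn0015714, 2R:10761458-10763063) had 46.0 ± 3.31 against 1.19 ± 0.167 CPM, Cyp6a2 114.8 ± 5.39 against 28.5 ± 1.98 CPM, and Cyp6a20 19.3 ± 2.25 against 94.0 ± 7.26 CPM. The list call was lost with DESeq2, limma-voom, total counts only, the stricter filter, thinned counts, the replicate block, fry and without w1118 replicate 2 (adjusted p from 0.00831 to 0.466 over settings with the preset correlation). In the muscle list 7 of 20 fell and 1 rose, with 8 and 1 adjusted over the list alone (camera adjusted p = 0.0278, and adjusted p = 0.922 with an estimated correlation). TpnC41C was 1.85-fold and Tm1 1.33-fold lower, and Mlp84B 1.30-fold higher. Without w1118 replicate 2, 1 fell, 2 fell without w1118 replicate 1 or Adar5G1 replicate 1, 4 without Adar5G1 replicate 3, and 3 with total counts only. The list call was lost with the stricter filter, with fry, and without Adar5G1 replicate 1 or 3 or w1118 replicate 2 (adjusted p from 0.0029 to 0.0777 over settings with the preset correlation). Without w1118 replicate 1 the calls of TpnC41C, Tm1 and Mlp84B were lost, that of Tm1 also without Adar5G1 replicate 1 or w1118 replicate 2, and that of Mlp84B without w1118 replicate 3. Of 28 midgut enzyme genes listed 4 were tested and 3 rose, also 3 adjusted over the list alone (camera adjusted p = 4.35e-06, and adjusted p = 0.207 with an estimated correlation). These were the amylase genes Amy-d (11.4-fold) and Amy-p, which are close copies, and LManII, an alpha-mannosidase (2.94-fold). Both amylase genes passed the count filter through Adar5G1 only, since not every w1118 library reached its cutoff. Members low in both groups were not tested, so the filter favours rises in this list test. Amy-p had 254 counts against 2, a count ratio scaled by library size of 111 (counting interval 30.3 to 919). The 2 w1118 counts of Amy-p were in replicate 3. Its fitted log2 fold change of 6.50 was 9.34 without that library and 5.61 without w1118 replicate 2.

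Of 25 ion channel and synaptic transcripts known to be edited 3 rose, also 3 adjusted over the list alone: nAChRalpha6 (1.87-fold), Syt1 (1.43-fold) and qvr (1.43-fold). Their list was not called (camera adjusted p = 0.588). In Adar5G1 replicates 1, 2 and 3 nAChRalpha6 had 329.4, 339.8 and 508.9 CPM and Syt1 1822, 1757 and 2284 CPM. Without both libraries numbered 3, a comparison chosen after the results were seen, 3 edited transcripts rose and 6 fell, the median log2 fold change was -0.11 and the direction was down (camera adjusted p = 0.213). Without w1118 replicate 1 or with the replicate block 0 passed in either direction. Rises numbered 1 without Adar5G1 replicate 1 and without w1118 replicate 2 or 3, and 5 with DESeq2. Of 20 neuronal markers 1 rose, Ddc (1.45-fold), and 0 adjusted over the list alone (camera adjusted p = 0.823). Without both libraries numbered 3, 2 rose and 3 fell. Of 24 neuropeptide genes 8 rose and 1 fell, the same numbers adjusted over the list alone (camera adjusted p = 0.106). The rises numbered 4 without Adar5G1 replicate 1 or w1118 replicate 1, 5 without Adar5G1 replicate 2 or w1118 replicate 3, and 3 with total counts only. CNMa was 8.51-fold and Proc 1.54-fold higher, and the insulin-like peptide gene Ilp3 2.32-fold lower. Of 12 clock genes 2 rose and 2 fell, with 3 and 2 adjusted over the list alone (camera adjusted p = 0.823). Their median log2 fold change was -0.07 and their mean 0.20. The takeout gene to had 253.5, 763 and 209.5 CPM in Adar5G1 against 38.6 ± 3.57 CPM, a log2 fold change of 3.40 that was 2.59 without Adar5G1 replicate 2. The gene vri was 1.43-fold higher and cyc 1.37-fold lower. Without w1118 replicate 2, 2 clock genes rose and 0 fell, and with total counts only 1 rose and 0 fell. Of 15 glial markers 3 rose and 2 fell, with 3 and 4 adjusted over the list alone (camera adjusted p = 0.357), among them Indy (1.74-fold higher), bdl (1.67-fold lower) and Gli (1.38-fold lower). Among glial markers 0 rose and 1 fell without w1118 replicate 1. Without Adar5G1 replicate 2, 1 rose and 1 fell, and with total counts only 1 rose and 0 fell. Of 19 antennal genes 2 rose and 4 fell, with 2 and 6 adjusted over the list alone (camera adjusted p = 0.329). Obp56d and Obp59a were 1.499-fold and 1.81-fold higher and Obp57c 1.69-fold lower. Falls of antennal genes numbered 2 without w1118 replicate 1 and 0 with total counts only. Without w1118 replicate 1 the calls of nAChRalpha6, Syt1, qvr, Ddc, Indy and Gli were lost, and without w1118 replicate 2 those of Syt1, qvr and cyc. Those of Syt1 and qvr were also lost without Adar5G1 replicate 1 or w1118 replicate 3, that of Ddc without either library numbered 3, and that of Gli without Adar5G1 replicate 2. Without w1118 replicate 2 the neuropeptide (adjusted p = 0.0363) and antennal (0.0323) lists passed.

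Of 9 tested fat body and yolk protein genes 4 rose and 2 fell, with 4 and 3 adjusted over the list alone (camera adjusted p = 0.823). Fbp1 was 9.42-fold and Lsp1gamma 6.21-fold higher, both with means under 2 CPM in Adar5G1, and tobi, a target of insulin signalling, 9.01-fold lower. Without w1118 replicate 2, 0 rose and 4 fell and the list was called lower (camera adjusted p = 0.0133). Without Adar5G1 replicate 1, 1 rose and 2 fell, and 2 rose without Adar5G1 replicate 2 or w1118 replicate 1 or 3. Fbp1 had 1.33, 3.25 and 1.10 CPM in the Adar5G1 libraries. Of 16 heat shock genes 2 fell, with 1 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.329). Hsc70-3 was 1.36-fold lower. Hsp70Ba, one of several close copies, had 0 counts in Adar5G1 and 81 in w1118, with 4.76, 0.943 and 2.48 CPM in the w1118 libraries. After scaling by library size it was at least 30.98-fold lower. Heat shock genes that fell numbered 5 without w1118 replicate 2 and 4 with DESeq2. Of 21 autophagy genes 3 rose, also 3 adjusted over the list alone (camera adjusted p = 0.381): Atg4a (1.36-fold), Atg17 (1.21-fold) and Atg2 (1.21-fold). Of the autophagy genes 0 rose without w1118 replicate 1 or with total counts only, and 1 rose without Adar5G1 replicate 1 or w1118 replicate 2. Of 6 mitochondrially encoded genes mt:ND5 rose (1.37-fold), also 1 adjusted over the list alone (camera adjusted p = 0.329). Of 21 nuclear oxidative phosphorylation genes 0 passed with edgeR, DESeq2 or limma-voom, 1 had an unadjusted p under 0.05, and 0 passed adjusted over the list alone (camera adjusted p = 0.381). The ATP synthase gene blw had 1248 ± 173 against 1324 ± 29.9 CPM. The 1 tested male reproductive gene, janB, which overlaps janA, had 0.536 ± 0.224 against 1.03 ± 0.322 CPM. With total counts only, 20 of the named genes in all lists no longer passed. The calls of Atg4a, Atg17 and Atg2 were lost without w1118 replicate 1, those of Fbp1 and Lsp1gamma without w1118 replicate 2, that of mt:ND5 without Adar5G1 replicate 1, and that of tobi with limma-voom or robust dispersion. Those of Atg17 and Atg2 were also lost without Adar5G1 replicate 1 or w1118 replicate 2, that of Atg17 without w1118 replicate 3, that of Atg2 without Adar5G1 replicate 2 or 3, and that of Lsp1gamma without Adar5G1 replicate 1 or w1118 replicate 3. The heat shock list passed without w1118 replicate 2 and with total counts only (lowest adjusted p = 0.00347).

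Changed genes were less frequent on the X chromosome, which carries Adar, y, sc and w. Of 1655 tested X-linked genes 183 changed (11.1%), against 1217 of 8415 on the other arms (14.5%). The odds ratio was 0.735 (95% interval 0.620 to 0.869, 2-sided Fisher's exact test p = 2.19e-04). Genes are not independent replicates. Within X, 40 of 344 genes below 5 Mb changed (11.6%), against 143 of 1311 elsewhere (10.9%), with an odds ratio of 1.07 (0.721 to 1.57, exact p = 0.700).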

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

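Of the settings compared, protein-coding genes only, thinned counts and leaving out both libraries numbered 3 were chosen after the results were seen. Changed genes numbered 582 higher and 209 lower with total counts only, 484 and 278 with the replicate block, 456 and 248 at an adjusted p of 0.01, and 448 and 167 with a 2-fold minimum; the last 2 follow from the stricter threshold and for the others the cause was not tested. Leaving out 1 library gave 545 to 1024 higher and 331 to 515 lower genes. The lowest counts were without w1118 replicate 1. With an estimated correlation 0 lists passed in place of 8 (4 at an unadjusted p under 0.05), and the antimicrobial peptide list, at a median of 8.82, had an adjusted p of 0.207, against 4.39e-92 to 1.62e-04 over the settings with the preset correlation. Leaving out 1 library moved that median between 7.44 and 9.16 and the number of lists between 7 and 11. The X odds ratio stayed between 0.639 and 0.767 over 21 settings. Without w1118 replicate 2 the fat body list was called lower (adjusted p = 0.0133) though its median was 0.07, and medians over the left-out libraries ran from 0.012 to 0.951; the cause was not tested. The heat shock, neuropeptide, hemocyte and antennal lists passed without that library too. With fry 8 lists passed, with the autophagy and neuropeptide lists in and the muscle and P450 lists out. Of 64 named genes past the threshold 34 stayed past it in each setting that tested them, 30 lost the call in at least 1, and 0 changed sign. Same-numbered libraries had deviations from their group means correlated at 0.20, -0.22 and -0.34 over 7898 genes. The libraries numbered 1 correlated best with each other, while Adar5G1 replicate 3 correlated best with w1118 replicate 2 (0.42). So not every library correlated best with its own number. Deviations from a mean of 3 libraries sum to 0, so these values cannot exclude a shared batch. With 3 libraries per group 41.8% of simulated 1.5-fold changes were recovered, where depth was not varied. Counts thinned to the smallest library gave 774 higher and 428 lower genes. With the replicate block 5 photoreceptor genes fell and 0 rose, 4 neuropeptide genes rose, 0 autophagy genes and 0 glial markers rose, 0 clock genes fell and 2 muscle genes fell. It also gave 14 Toll, 6 IMD and 2 fat body genes higher, 1 heat shock gene lower, and 12 P450 and transferase genes higher and 6 lower. Of the named genes 14 no longer passed with the block, among them Dcr-2, Hsc70-3, nAChRalpha6, Indy, TpnC41C, Tm1 and Mlp84B.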

Other observations

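The main results had been seen before the patterns below and their explanations were chosen. The tests on fat body tissue, on other differences between the stocks, on photoreceptor tissue share and on gene families were chosen after the values they measure were seen. The reading of the test on stretches of DNA as open was settled after its value was seen. Gene families defined by the leading letters of gene symbols, 77 with at least 8 tested members, were compared with all tested genes in each direction by Fisher's exact test. Each of the 12 tested Bomanin genes rose (edgeR; exact enrichment adjusted p = 3.2e-11), as did 6 of 10 peptidoglycan recognition protein genes (exact adjusted p = 0.00367). Genes with symbols starting in Cyp, mostly cytochrome P450 genes, were over-represented in both directions, with 21 of 70 higher (exact adjusted p = 2.58e-05) and 11 lower (exact adjusted p = 0.0307). Ribosomal protein genes were under-represented among rises, with 0 of 79 higher (exact adjusted p = 0.0336) and 0 lower (exact adjusted p = 0.445). Past the threshold were 0 with edgeR, DESeq2 or limma-voom, and 4 had an unadjusted p under 0.05.

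Among 10 splits of the 6 libraries into 3 and 3, the real one gave 1423 changed genes and the highest other 0. With 10 splits the share cannot go under 0.05; 1 split, the real one, gave as many.

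Of 11 antimicrobial peptide genes 7 were higher in Adar5G1, in a list where the count filter favours rises. More fat body tissue in the mutant heads as the whole cause is argued against, as far as the fat body list measures it. The antimicrobial list's median with bounds was 6.57, while fat body members ranged from -3.17 to 3.24 on the log2 scale. The highest of these, Fbp1, had 6 counts over w1118, and without w1118 replicate 2 the fat body list was called lower. A part in the rise was not excluded. A single unusual library is argued against too, since at least 9 of the genes passed, higher, without each Adar5G1 library in turn; values per library had been seen when this test was chosen. Other differences between the 2 stocks cannot be told apart from the Adar mutation, because each genotype is 1 stock. There were 9 genes outside Adar, w and the lists at 1 CPM or more in each library of 1 stock and below 0.1 CPM in each of the other, 6 on in Adar5G1 and 3 in w1118. Those on in Adar5G1 included sordd2 and CG14204, named above among the largest rises. An effect of the Adar mutation, and a difference in microbes carried by the stocks, which was not tested, stay open.

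Of 25 photoreceptor genes 12 were lower in Adar5G1, and 21 were below 0, with a weighted mean log2 fold change of -0.34, as a shared fall would give. An equal fall of all members is argued against: they moved apart by more than their approximate standard errors, from -1.37 to 0.34 (Cochran's Q over 25 genes, p = 7.97e-41 by its chi-square approximation, which is not an exact test). A smaller share of photoreceptor tissue would lower them alike only if each were expressed in the same photoreceptors and nowhere else. That was not measured, so a smaller share was not excluded as the whole cause or a part of it. The list's median stayed below 0 under each of 4 scalings, the highest being -0.33. These scalings moved the median over all tested genes only from -0.059 to 0.008, too little to bring the list to 0. An effect of residual ribosomal RNA was therefore not tested. The Adar mutation and the difference in w, which alters eye pigment, stay open and were not separated.

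Changed genes were rarer on X than on the other arms together, though chromosome 4 had a lower share still (6 of 92 genes). Lower power from expression level or gene length is argued against: with both in a logistic model the odds ratio was 0.749, with an upper 95% bound of 0.884. Without the genes of all lists the upper bound was 0.932, so the lists do not account for it. Both bounds treat genes as independent. Changed genes on the autosomes lay side by side more often than in shuffles, so the bounds may be too narrow. No biological explanation was tested.

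A further hypothesis was that changed genes lie side by side on the autosomes because stretches of DNA differ between the stocks. Leaving out pairs sharing exons, 276 neighbouring pairs were both changed, against at most 203 in 1000 shuffles within arms (permutation p = 9.99e-04, the smallest they can give). Pairs changed in the same direction numbered 195, against at most 117. Pairs changed in opposite directions numbered 81, within the middle 95% of the shuffles (64 to 96). This is consistent with neighbouring genes that are regulated together, such as gene clusters. Stretches of DNA present in different copy number would also move neighbours the same way, so these cannot be told apart from regulation here.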
